A study of Mus musculus with 10 samples.

How the data were processed

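Total RNA from mouse rear ankle joints, with the skin removed, was measured on 10 Affymetrix arrays, each from a pool of at least 5 female mice aged 6 to 7 weeks. The mice belonged to 5 lines: the inbred strain C3H, 2 congenic lines with C3H background that carry a C57BL/6 (B6) interval (C3H.B6-Bbaa4 and C3H.B6-Bbaa2Bbaa3), and 2 with B6 background that carry a C3H interval (B6.C3H-Bbaa4 and B6.C3H-Bbaa2Bbaa3). The intervals come from linkage analysis of Lyme arthritis severity. Bbaa4 lies on chromosome 11, and Bbaa2 and Bbaa3 lie on chromosome 5, from general knowledge of these loci and not from the labels. Each line gave 1 pool injected with medium and 1 pool taken 1 week after injection of 2000 Borrelia burgdorferi, so each of the 10 groups holds 1 array. B6 mice without a C3H interval were not analysed here.

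The deposited values were on the log2 scale, for 45101 probe sets. The authors' normalization method is not named in the labels, and array medians ran from 2.974 to 3.410. The arrays fell into 3 sets by their value distributions and their rank correlations: the 2 C3H arrays, the 6 arrays of the lines labelled C3H.B6-Bbaa4, B6.C3H-Bbaa4 and C3H.B6-Bbaa2Bbaa3, and the 2 arrays of B6.C3H-Bbaa2Bbaa3. Spearman correlations over probe sets were 0.986 to 0.994 between lines of the same set and 0.895 to 0.960 between sets. The labels name no batch, so sets that were normalized or hybridised apart cannot be excluded.

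In the deposited table the rows of 6 columns were out of order. The values of those 6 arrays had a Spearman correlation of 0.06 to 0.063 with the uninfected C3H array, and probe sets for the same gene did not correlate in them (-0.001 to 0.002). The displaced values followed the table's own probe order laid onto rows ranked by the difference between the infected and uninfected C3H arrays, and they were put back by that ranking. After this the correlation with C3H was 0.952 to 0.960, and the correlation of 9012 pairs of probe sets for the same gene was 0.345 to 0.368, against 0.314 to 0.324 in the columns that had been in order. Over 270 windows of 1000 probe sets, the lowest correlation at the assigned place was 0.889 and the highest at a shift of 1 row was 0.665. For 264 probe sets the difference equalled a neighbour's within the printed rounding, so their place was unsettled and they were left out.

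Because array medians differed by more than 0.1, the values were quantile normalized with limma 3.58.1 in R 4.3.3. Probe sets with exactly 1 gene symbol were kept if their mean over the arrays was in the upper 60%, and the probe set with the highest mean stood for its gene, which left 13487 genes. Chromosomes came from the RefSeq annotation of GRCm38.p6. Each comparison was a linear model in limma (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Infection was tested with the line as a block (4 residual degrees of freedom). Background (C3H minus B6), the Bbaa4 allele and the Bbaa2Bbaa3 allele (each C3H minus B6) were terms of 1 additive model with infection (5 residual degrees of freedom), and infection by background was tested within lines (3 residual degrees of freedom). The p-values of the infection fit measure the spread of the infection change between lines, not between replicate pools or mice. In the background and allele fits the residual holds this spread and 1 degree of freedom between line means. For infection by background it is this spread among lines of the same labelled background. Groups were used as labelled.

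There were 25 gene lists of pathways and of cell types that an ankle sample may hold. Each list with at least 5 measured members was tested with limma's camera at its preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry as alternatives. Within each line, with 1 array against 1, only the genes changed at least 2-fold and the median change of each list were described, with its percentile among 10000 random lists matched on expression deciles. Called allele genes were counted by chromosome with Fisher's exact test. Genes are named by a rule: the 10 largest changes in each direction among genes past the threshold with the same sign among uninfected and among infected arrays (for infection, in all 5 lines), or the 5 with the smallest p where none passes; the 2 to 4 members of each discussed list with the smallest p; the strain genes H2-Ea, Gusb and Nnt and the sex genes; and the 5 largest rises and falls of each line. The comparisons, lists, naming rule and first alternatives were fixed before the data were examined. The row order, the array sets and the genes used to compare the labels with the genotypes were examined only after the values had been seen.

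The models were tested on simulated data with 200 changed genes, drawn at random and changed by the same amount in every line, with independent noise in each array. In the data the 2 arrays of a line are not independent, and infection changes of many genes varied widely between lines. The shares recovered can therefore be higher than in the data. The infection model recovered 87.5% of changes of 1 log2, the background model 42.1%, the Bbaa4 model 14.6%, the Bbaa2Bbaa3 model 16.1% and the interaction model 23.3%; for changes of 2 log2 these were 98.8%, 89.3%, 78.2%, 78.5% and 84.5%. The alternatives were the deposited normalization, a floor at the 20th percentile, no filter, the upper 40%, the mean of a gene's probe sets, a variance prior with trend and robust, other sets of terms or lines, and leaving out each line or array. Added after the data were seen were fits to the 4 arrays in order or to the 6 reordered arrays, rows left as deposited, unsettled probe sets kept, an array set block, line means with allele terms, and exchanged labels of the 2 Bbaa4 lines. The number of arrays limits the precision of every value. Figures were drawn with matplotlib 3.10.9.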

Results

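Gene expression was measured in ankle joint RNA of 5 mouse lines, each with 1 uninfected pool and 1 pool taken 1 week after infection with Borrelia burgdorferi, the agent of Lyme disease. C3H mice develop severe Lyme arthritis and B6 mice mild disease, and the congenic lines carry intervals linked to severity on the opposite background. No group has replicate arrays, so values within a line are given without error, and values averaged over lines carry the SD over the 5 lines. All arrays had the female pattern of sex genes, with Xist at 8.69 to 11.49 and the Y-linked genes Eif2s3y at 2.87 to 3.20, Kdm5d at 2.55 to 2.68 and Uty at 3.34 to 4.36. For comparison, 20% of all probe set values lay below 2.35. Ddx3y was not named on the array.

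The rows of 6 arrays had to be put back in order before use. The plot of row order gives the correlation of each array with the uninfected C3H array before and after this step.

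**Figure D1:**
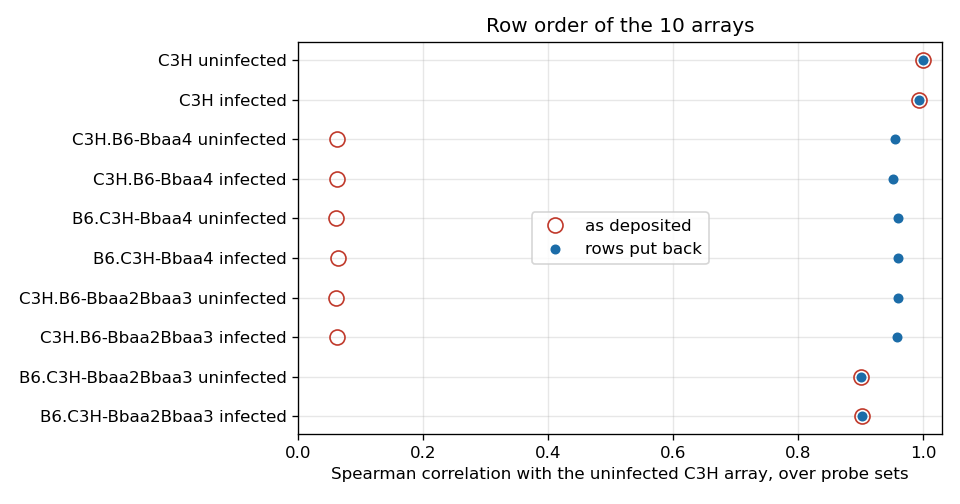
Spearman correlation over probe sets (x axis) of each array (y axis) with the uninfected C3H array, as deposited (open circles) and after the rows were put back (filled circles). The 6 arrays with displaced rows lay at 0.06 to 0.063 as deposited and at 0.952 to 0.960 afterwards.

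Genes with strong differences between lines were compared with the genotypes in the labels, after their values had been seen. H2-D1, a class I major histocompatibility gene, lay at 13.37 to 14.92 in C3H, C3H.B6-Bbaa2Bbaa3 and the arrays labelled B6.C3H-Bbaa4, and at 6.29 to 7.04 in B6.C3H-Bbaa2Bbaa3 and the arrays labelled C3H.B6-Bbaa4. The secreted phospholipase gene Pla2g2a, the interferon-inducible gene Ifi202b and the mast cell tryptase gene Tpsab1 had the same order, with Pla2g2a at 10.50 to 11.51 in the first 3 lines and 2.97 to 3.32 in the other 2. Trim34a lay at 2.5 to 2.88 in the first 3 and 6.63 to 7.37 in the other 2. None of these genes is on chromosome 5 or 11, where the intervals lie. By their labels the first 3 lines have C3H, C3H and B6 background, and the other 2 have B6 and C3H background. The arrays labelled B6.C3H-Bbaa4 and those of C3H.B6-Bbaa2Bbaa3 differed by at least 2 log2, in the same direction among uninfected and among infected arrays, in 8 genes, of which 7 were on chromosome 11 and 1 on chromosome 5. The arrays labelled C3H.B6-Bbaa4 differed from C3H.B6-Bbaa2Bbaa3 in 155 genes, 135 of them on other chromosomes. Over all genes off chromosomes 5 and 11 that differed by at least 2 log2 both between the 2 Bbaa4 lines and between C3H and B6.C3H-Bbaa2Bbaa3, the line labelled C3H.B6-Bbaa4 departed from the line labelled B6.C3H-Bbaa4 in the direction of C3H in 57 genes and in the opposite direction in 23. C3H and B6.C3H-Bbaa2Bbaa3 belong to different array sets, so this direction mixes array set with background and tests neither. The line labelled C3H.B6-Bbaa4 also departed from C3H.B6-Bbaa2Bbaa3, of the same labelled background, in the direction of C3H in 39 such genes. In 23 it departed in the opposite direction. Of the strain genes fixed beforehand, H2-Ea (3.98 to 5.60) and Nnt (10.63 to 11.46) did not part the lines by labelled background. Gusb, on chromosome 5, lay at 9.74 to 10.56 in lines labelled as C3H background and at 8.45 to 9.64 in those labelled as B6 background, where B6.C3H-Bbaa2Bbaa3 was at 8.45 to 8.96. It was fixed for a hypomorphic allele in C3H, which gives no reason for higher values in lines labelled as C3H background. The groups below are as labelled, and each result that uses the background or an allele of the 2 Bbaa4 lines rests on those labels.

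**Figure D2:**
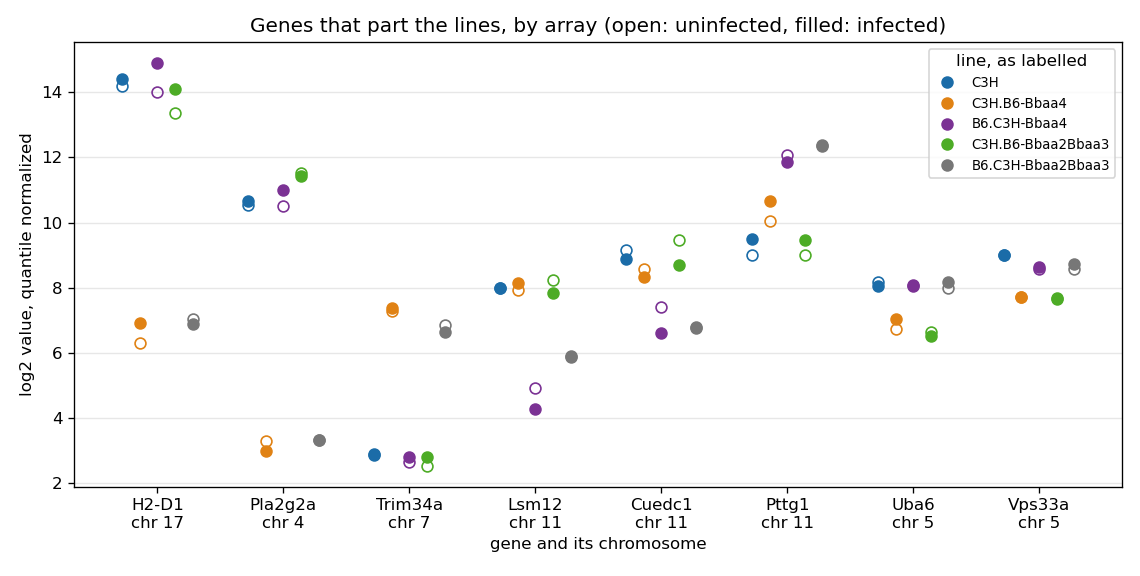
Quantile normalized log2 values (y axis) of 8 genes (x axis, with chromosome) in each array, coloured by labelled line, open for uninfected and filled for infected. H2-D1, Pla2g2a and Trim34a set the arrays labelled C3H.B6-Bbaa4 beside B6.C3H-Bbaa2Bbaa3; Lsm12 lay at 4.59 on average in the line labelled B6.C3H-Bbaa4 and at 8.04 in the line labelled C3H.B6-Bbaa4.

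The infection comparison asked what changed in the joint 1 week after injection, averaged over the lines. By camera with its preset correlation, interferon-inducible genes, inflammatory mediators and cell cycle genes rose as groups, and adipocyte and red cell genes fell; with an estimated correlation none of these lists passed (adjusted p = 0.255 for each). The interferon-gamma list (GTPases that act against pathogens inside cells, and T cell chemokines) rose by a median of 2.5 log2, with 15 of 15 members above 0 (camera adjusted p = 1.89e-14). The type I interferon list rose by 1.25, with 28 of 28 above 0 (adjusted p = 3.89e-19), inflammatory cytokines and chemokines by 1.05, with 19 of 20 above 0 (adjusted p = 1.79e-14), and pattern recognition and NF-kB genes by 0.59, with 20 of 21 above 0 (adjusted p = 1.89e-14). Antigen presentation rose by 0.67 (17 of 17 above 0, adjusted p = 9.96e-13), and cell cycle genes by 0.47 (16 of 17, adjusted p = 1.12e-12). The adjusted p of 0.255 with an estimated correlation held for each of these 6 lists. Adjusted over the list alone, 13 interferon-gamma genes, 12 type I interferon genes, 9 cytokine genes, 10 pattern recognition genes, 5 cell cycle genes and 0 antigen presentation genes were higher; over all genes tested the count was 0 in each list.

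No gene passed the threshold over all 13487 genes in limma, where the smallest adjusted p was 0.220; 656 genes were higher and 750 lower at an unadjusted p under 0.05. The higher genes with the smallest p were Cdk1, the kinase that drives mitosis (0.62 ± 0.04, SD over 5 lines), the acute phase gene Saa1 (3.76 ± 0.84), the fungal receptor gene Clec7a (0.58 ± 0.11), the inflammasome gene Naip2 (0.84 ± 0.22) and Efhd2 (0.68 ± 0.18), all above 0 in 5 of 5 lines. The lower ones were the muscle stress gene Ankrd2 (-1.0 ± 0.25), Spsb4 (-0.64 ± 0.18), Slurp1 (-0.65 ± 0.22), Eif2b3 (-0.29 ± 0.03) and Nnat (-0.79 ± 0.29), all below 0 in 5 of 5. Cdk1 passed when no probe sets were filtered out (adjusted p = 0.0243), Saa1 with the upper 40% of probe sets (adjusted p = 0.0226), and Saa3 without C3H (adjusted p = 0.0247). The members with the smallest p of the interferon-gamma list were Gbp3 (2.95 ± 1.62), Gbp7 (2.5 ± 1.43), Gbp2 (2.56 ± 1.59) and Cxcl9, a chemokine for T cells (3.72 ± 2.48), and of the type I interferon list Eif2ak2 (0.97 ± 0.40), Parp14 (1.92 ± 0.90), Oasl2 (2.93 ± 1.49) and Ifit1 (3.55 ± 2.15). For cytokines they were the neutrophil chemokine gene Cxcl1 (1.38 ± 0.43), the monocyte chemokine genes Ccl12 (3.68 ± 1.24) and Ccl8 (1.63 ± 0.73), and Il1b (2.54 ± 1.29), and for pattern recognition the acute phase gene Saa3 (5.32 ± 2.24) and Nfkbiz (1.51 ± 0.70). For antigen presentation they were the proteasome genes Psmb9 (1.93 ± 1.28) and Psmb10 (1.21 ± 0.87), the peptide transporter gene Tap1 (2.35 ± 1.72) and Psmb8 (1.74 ± 1.27). None of these passed the threshold over 10 arrays. The uninfected value of Ccl12 in B6.C3H-Bbaa2Bbaa3 (1.80) lay below 3.22, the median of all probe set values, so the size of its change is not exact.

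Other lists that rose with infection were monocyte and macrophage genes (median 0.21, adjusted p = 6.10e-07, 4 members higher adjusted over the list alone), matrix remodelling enzymes (0.29, adjusted p = 6.78e-06, 2 members), neutrophil genes (0.44, adjusted p = 6.69e-05, 0 members) and cartilage genes (0.28, adjusted p = 7.78e-05, 0 members). Their adjusted p with an estimated correlation was 0.255, 0.255, 0.438 and 0.296. Neutrophil genes had a median of 1.58 in C3H and -0.53 in B6.C3H-Bbaa2Bbaa3, where 1 of 16 was above 0, and without C3H the median of neutrophil under infection was 0.13. The collagenase gene Mmp13 averaged 0.89 ± 0.39 and the stromelysin gene Mmp3 1.63 ± 0.82. Adipocyte genes fell (median -0.26, 0 of 14 above 0, adjusted p = 1.51e-06), with the hormones Lep at -0.79 ± 0.32 and Adipoq at -0.33 ± 0.10, and 5 members were lower adjusted over the list alone. Epidermis genes (-0.60, adjusted p = 0.00489), skeletal muscle genes (-0.12, adjusted p = 0.00513) and erythroid genes (-0.43, adjusted p = 0.00807) also fell. For these 4 lists the adjusted p with an estimated correlation was 0.255, 0.587, 0.346 and 0.255. The epidermis fall came from B6.C3H-Bbaa2Bbaa3 (-2.69, against -0.06 to 0.00 in the other lines). Without that line the median of epidermis and cornified envelope under infection was -0.033 (camera adjusted p = 0.587). In the other lines some members were low: Sprr1b averaged 2.45 to 2.51 and Lgals7 2.37 to 2.55. These lay below 3.22, the median of all probe set values, so their changes there say little. Other members were not low there, such as Krtdap at 9.52 to 10.85. Without C3H.B6-Bbaa2Bbaa3 the adjusted p of skeletal muscle under infection was 0.0532. The other 11 lists did not pass: osteoclast (median 0.20), osteoblast (0.08), immediate early and heat shock (0.03), lysosomal hydrolase (0.01), fibroblast (-0.02), nerve and Schwann cell (-0.05), T and NK cell (-0.07, with a mean of 0.15), B cell (-0.13), plasma cell (-0.18), endothelial (-0.19) and mast cell (-0.21).

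Line by line, the infection change of interferon genes had 2 sizes. The interferon-gamma list had a median change of 4.12 in C3H, 4.44 in the line labelled B6.C3H-Bbaa4 and 3.24 in C3H.B6-Bbaa2Bbaa3, against 0.88 in the line labelled C3H.B6-Bbaa4 and 0.48 in B6.C3H-Bbaa2Bbaa3. Cxcl9 was 5.33, 5.96 and 5.26 higher in the first 3 lines and 1.22 and 0.84 higher in the other 2. The type I interferon list had medians of 1.81, 2.89 and 1.34 against 0.42 and 0.06. Inflammatory genes were arranged otherwise: Saa3 was 1.39 higher in C3H and 5.82 to 6.99 higher in each other line, and Il1b was 0.32 higher in C3H and 2.55 to 3.49 higher elsewhere. The cytokine list had a median of 0.02 in C3H, 1.11 in the line labelled C3H.B6-Bbaa4, 2.27 in the line labelled B6.C3H-Bbaa4, 1.21 in C3H.B6-Bbaa2Bbaa3 and 0.37 in B6.C3H-Bbaa2Bbaa3. These differences between lines rest on 1 array against 1 and were not tested.

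**Figure D3:**
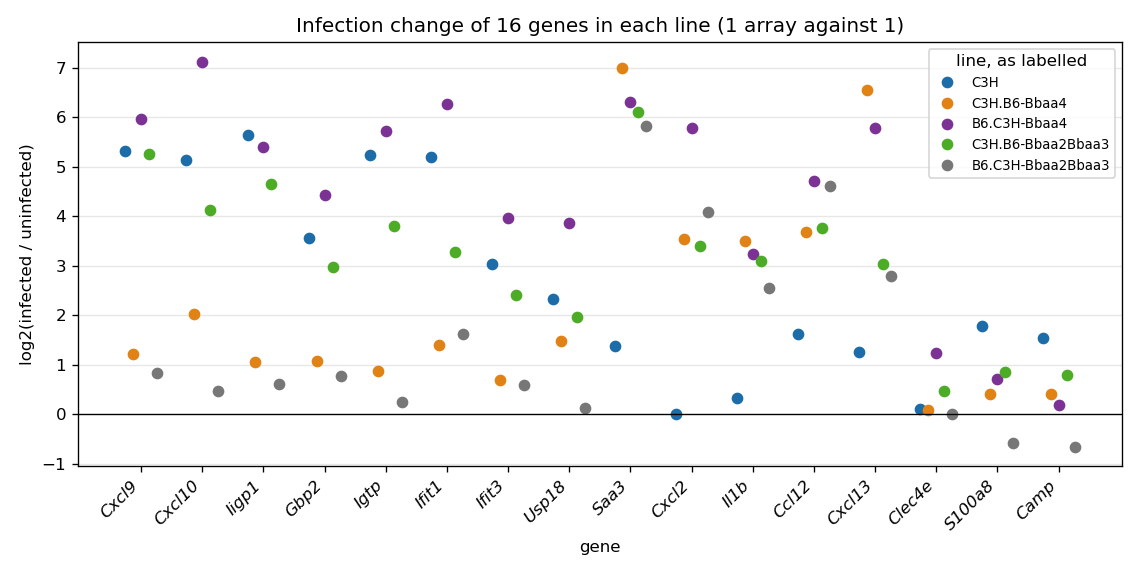
Log2 infected over uninfected value (y axis) of 16 genes chosen after their values were seen (x axis) in each labelled line, 1 array against 1. The interferon genes at the left were far higher after infection in C3H, C3H.B6-Bbaa2Bbaa3 and the line labelled B6.C3H-Bbaa4, while Saa3, Cxcl2 and Il1b had their smallest change in C3H.

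After infection, 342 genes were at least 2-fold higher and 218 lower in C3H. The counts were 169 and 283 in the line labelled C3H.B6-Bbaa4, 327 and 173 in the line labelled B6.C3H-Bbaa4, 212 and 213 in C3H.B6-Bbaa2Bbaa3, and 95 and 115 in B6.C3H-Bbaa2Bbaa3. Ccl12, Clec4d, Cxcl13, Fcgr1, Gbp3, Ifit1, Saa1, Saa3 and Slfn4 were at least 2-fold higher in all 5 lines, and 0 genes were 2-fold lower in all. C3H shared 140 of its 2-fold higher genes with the line labelled B6.C3H-Bbaa4, where 8.29 would be shared by independent lists, and 27 with the line labelled C3H.B6-Bbaa4 (4.29 for independent lists). The largest changes in C3H were in the hair keratin gene Krt25 (6.03), the interferon-inducible genes Iigp1 (5.64), Cxcl9 (5.33), Gbp2b (5.30) and Igtp (5.24), and the ribonuclease gene Rnase2a (-5.39). In the line labelled C3H.B6-Bbaa4, Saa3 (6.99), the B cell chemokine gene Cxcl13 (6.56) and the carrier gene Slc13a3 (5.52) were highest, and Krtap8-1 (-6.37) and Krt25 (-5.66) had the largest falls. Gbp2b (7.39) and Cxcl10 (7.12) led in the line labelled B6.C3H-Bbaa4, where the signalling gene Shh was lowest (-3.83), and Saa3 (6.10) and Ccl2 (5.15) were among the highest in C3H.B6-Bbaa2Bbaa3. In B6.C3H-Bbaa2Bbaa3, Slc13a3 (6.18) and Saa3 (5.82) were highest, and Krt2 (-7.54), Gm94 (-5.90), Calm4 (-5.81), Hrnr (-5.75) and Dsp (-5.64) had the largest falls. The infected values of Krtap8-1 (1.95) and Krt25 (3.02) in the line labelled C3H.B6-Bbaa4 and of Gm94 (2.45), Krt2 (2.74) and Hrnr in B6.C3H-Bbaa2Bbaa3 lay below 3.22, the median of all probe set values. So did the uninfected value of Cxcl13 (3.20) in the line labelled C3H.B6-Bbaa4, and the uninfected value of Krt25 in C3H was 3.24, so the sizes and ranks of these changes are not exact.

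**Figure D4:**
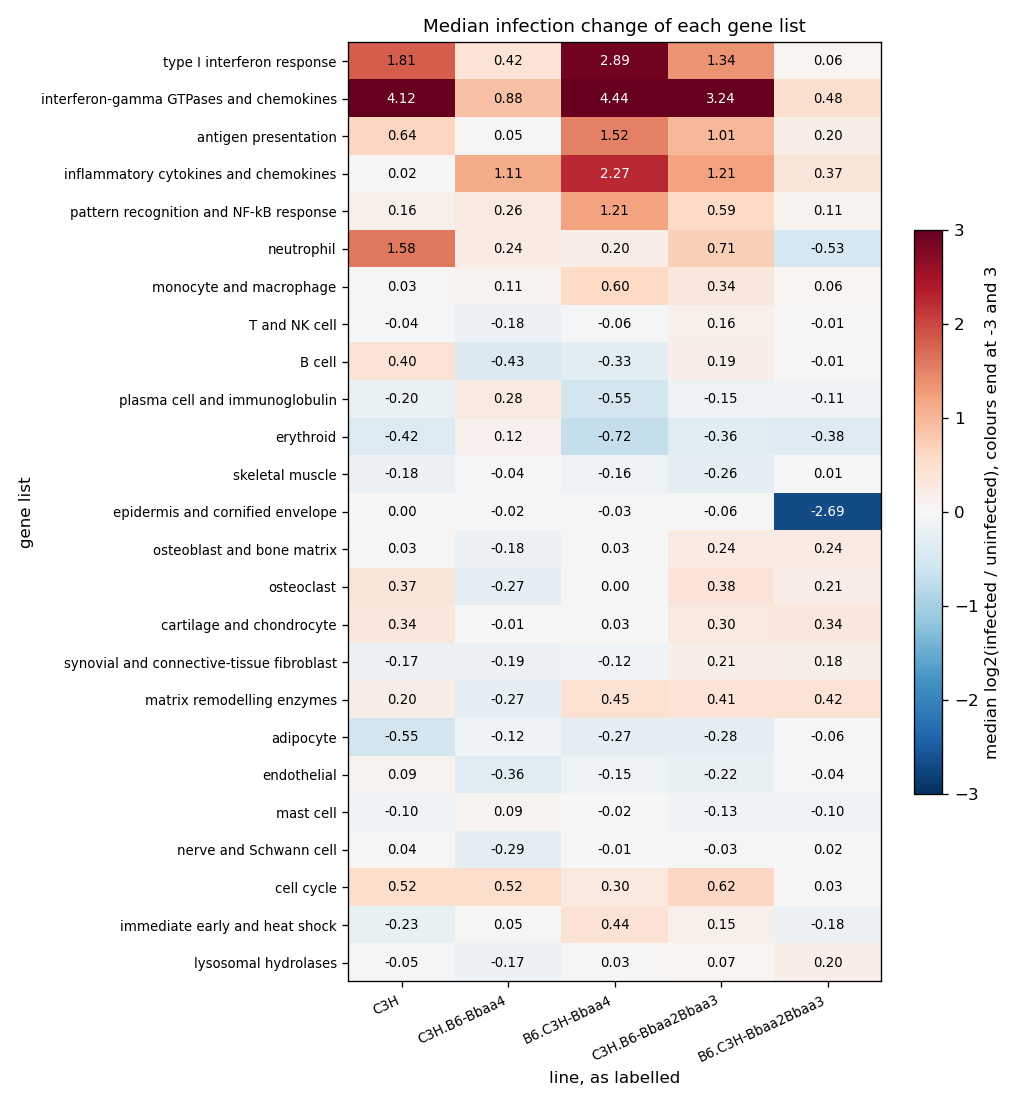
Median log2 infected over uninfected value (colour and number) of each of the 25 gene lists (y axis) in each labelled line (x axis), 1 array against 1. The interferon-gamma list ran from 0.48 to 4.44, and the epidermis list was at -2.69 in B6.C3H-Bbaa2Bbaa3 and between -0.06 and 0.00 in the other lines.

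The background comparison asked which genes differ between lines labelled as C3H and as B6 background, with both intervals as terms. Higher in lines labelled as C3H background were Gas7 (3.54 ± 0.29, SE), Lsm12 (2.80 ± 0.29), the matrix glycoprotein gene Thbs1 (2.01 ± 0.21), Cuedc1 (1.88 ± 0.18) and Ppp4r3b (1.05 ± 0.10), with adjusted p of 0.0411 to 0.0484 in a model that counts the 2 arrays of a line as independent. The background term was negative, with adjusted p in the same range, for Pttg1 (-2.38 ± 0.22), Cahm (-2.08 ± 0.19), the ubiquitin-activating enzyme gene Uba6 (-1.34 ± 0.13) and Vps33a (-0.93 ± 0.10). With 1 mean per line, 3 lines against 2 without allele terms, limma called 0 genes (smallest adjusted p 0.561, 772 at an unadjusted p under 0.05), and with allele terms also 0 (0.855, 231). Uba6 and Vps33a did not part the lines by background: they averaged 8.11 and 9.0 in C3H, the highest of the 5 lines, 6.58 and 7.67 in C3H.B6-Bbaa2Bbaa3, and 8.08 and 8.65 in B6.C3H-Bbaa2Bbaa3. Of these 9 genes 5 were on chromosome 11 and 2 on chromosome 5, which together hold 14.4% of the tested genes (Fisher's exact p = 3.55e-05, two-sided, chosen after the genes were seen). At an unadjusted p under 0.05 there were 2025 higher and 2783 lower genes.

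By list, camera with its preset correlation called genes of blood-forming and skeletal cells higher in lines labelled as C3H background, with adjusted p of 0.622 for each of these 5 lists at an estimated correlation: neutrophil (median 1.87, adjusted p = 0.000411), erythroid (1.88, adjusted p = 0.000480), B cell (1.79, adjusted p = 0.000681), cell cycle (1.34, adjusted p = 0.000480) and osteoblast genes (1.12, adjusted p = 1.82e-05). The cell cycle members with the smallest p were Mki67 (1.18) and Mcm2 (1.34), and those of the osteoblast list the phosphatase gene Alpl (0.92) and Col1a2 (0.50). The osteoclast (0.99), matrix remodelling (0.73), endothelial (0.50), fibroblast (0.49), monocyte (0.43), lysosomal (0.42), immediate early (0.39) and cartilage (0.20) lists were also called higher, with adjusted p from 0.000480 to 0.0458. Epidermis genes (-1.14, adjusted p = 0.0122) and skeletal muscle genes (-0.70, adjusted p = 0.00151) were lower. In the fit with the array set as a block, described below, neither of these lists had a negative median. With the labels of the 2 Bbaa4 lines exchanged the skeletal muscle median was positive. With an estimated correlation the adjusted p of all these 15 lists ran from 0.622 to 0.695. Adjusted over the list alone, 11 osteoblast genes, 7 fibroblast genes, 5 endothelial genes, 3 monocyte genes, and 1 gene each of the B cell, erythroid and cell cycle lists were higher; over all genes tested the count was 0 in each list. With the array set as a block the count of genes was 0 (smallest adjusted p 0.0550; 1547 at an unadjusted p under 0.05), and this fit compares C3H.B6-Bbaa2Bbaa3 alone with the line labelled B6.C3H-Bbaa4. In it the median of neutrophil under background was -0.16 (adjusted p = 0.971), of B cell under background -0.18 (adjusted p = 0.615) and of cell cycle under background -0.091 (adjusted p = 0.811), so these 3 lists were not called higher in C3H.B6-Bbaa2Bbaa3 than in the line labelled B6.C3H-Bbaa4. The myeloperoxidase gene Mpo, singled out after its values were seen, lay at 7.19 to 7.63 in B6.C3H-Bbaa2Bbaa3, a set of its own, and at 11.09 to 13.46 in the other 4 lines. Leaving out each array in turn gave 0 genes, except for 1 without the uninfected C3H.B6-Bbaa2Bbaa3 array and 9 without the infected array labelled B6.C3H-Bbaa4, of which 0 were among these 9. With the labels of the 2 Bbaa4 lines exchanged the count of background genes was 101, 0 of them among these 9.

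The allele comparisons asked which genes follow the C3H or B6 form of each interval. At Bbaa4, 775 genes were higher and 397 lower with the C3H allele; on the values as deposited the balance turned, with 305 higher and 611 lower. This model also counts the 2 arrays of a line as independent; with 1 mean per line and the same terms, which leave 1 residual degree of freedom, limma called 0 genes for Bbaa4 (smallest adjusted p 0.458, 455 at an unadjusted p under 0.05) and 0 for Bbaa2Bbaa3 (smallest adjusted p 1.0, 388 at an unadjusted p under 0.05). The highest were H2-D1 (7.81 ± 0.26, SE, adjusted p = 0.000196), Pla2g2a (7.24 ± 0.30, adjusted p = 0.000352), the interferon-inducible GTPase gene Gbp8 (6.08 ± 0.70), Ifi202b (6.04 ± 0.46), Tmem87a (5.37), Cap1 (4.55), Tpsab1 (4.50), Pik3ap1 (4.39), Sorbs3 (4.25) and Tnks1bp1 (3.72). The lowest were Rpgrip1 (-5.79 ± 0.47), Ahnak2 (-4.92 ± 0.21), Nxpe4 (-4.79), Ecpas (-4.67), Pdxdc1 (-4.56), Uchl1 (-4.36), Trim34a (-4.30), Ralgapa1 (-4.27), Ubtf (-4.20) and Zfp874a (-4.08). Adjusted p ran from 0.000196 to 0.0427, and of these 20 genes only Ubtf is on chromosome 11. Sorbs3 and Tnks1bp1 did not follow the labelled allele. They averaged 7.14 and 6.19 in C3H, against 2.39 to 3.26 and 2.43 to 2.56 in the other lines. Line means of Gbp8, Ecpas, Ralgapa1, Ubtf and Uchl1 also overlapped between the labelled Bbaa4 alleles. Ubtf averaged 3.52 in C3H, 7.12 in the line labelled B6.C3H-Bbaa4 and 7.92 in C3H.B6-Bbaa2Bbaa3. It averaged 8.54 in the line labelled C3H.B6-Bbaa4 and 4.51 in B6.C3H-Bbaa2Bbaa3. By line means Ecpas, Ralgapa1 and Ubtf set the reordered arrays apart from the others. With the mean of its probe sets, H2-D1 was at -0.24. Low line means of Ifi202b (2.91 and 3.08), Tmem87a (2.71 and 2.19), Ahnak2 (2.89 to 3.06), Nxpe4 (2.82 to 3.06) and Trim34a (2.65 to 2.87) lay below 3.22. That is the median of all probe set values, so the sizes and ranks of these differences are not exact. Cell cycle genes (median -1.07, adjusted p = 0.000425) and erythroid genes (-1.92, adjusted p = 0.00268) were lower, and adipocyte genes (0.55, adjusted p = 0.0250), with Lep at 2.58 and Retn at 1.55, and endothelial genes (0.60, adjusted p = 0.0358) were higher. The adjusted p of each was 0.889 with an estimated correlation. Adjusted over the list alone, 4 cell cycle genes and 1 erythroid gene were lower, against 2 and 1 over all genes; 5 adipocyte and 6 endothelial genes were higher, against 4 and 0.

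At Bbaa2Bbaa3, 828 genes were higher and 386 lower with the C3H allele; on the values as deposited 296 were higher and 1819 lower. The highest were the axon guidance gene Sema3f (4.92 ± 1.16, SE, adjusted p = 0.0456), Gbp8 (4.90 ± 0.70, adjusted p = 0.0114), Limk2 (3.85), Sorbs3 (3.84), Tnks1bp1 (3.77), Arrdc2 (3.70), 2810410L24Rik (3.56), Crtc2 (3.49), Srrd (3.47) and the cystathionine lyase gene Cth (3.37). The lowest were Ecpas (-6.50 ± 0.81), the eosinophil peroxidase gene Epx (-5.85 ± 1.39), Ralgapa1 (-5.61), Ubtf (-5.20), Scaper (-4.93), Nkap (-4.73), Rb1cc1 (-3.64), Nol9 (-3.53), Pggt1b (-3.30) and Uchl1 (-3.26). Of these 20 genes Gbp8, Srrd and Uchl1 are on chromosome 5. Several did not follow the labelled allele. Sema3f averaged 7.88 in C3H and 8.73 in B6.C3H-Bbaa2Bbaa3, but 4.03 in the line labelled C3H.B6-Bbaa4, which has the same allele by its label. Limk2, Ecpas, Ubtf, Scaper and Nkap also set the 6 reordered arrays apart from the other 4. Sorbs3 and Tnks1bp1 were high in C3H alone. The 4 arrays lay all above or all below the 6 in 44.9% of called genes, against 12.4% of other genes. Lower by list were cell cycle genes (median -1.40, adjusted p = 2.46e-05), neutrophil genes (-1.99, adjusted p = 0.000486), erythroid genes (-1.66, adjusted p = 0.00102), B cell genes (-2.04, adjusted p = 0.00330), cytokine genes (-0.61, adjusted p = 0.0236), osteoblast genes (-0.59, adjusted p = 0.0236) and plasma cell genes (-0.59, adjusted p = 0.0299). The adjusted p of each was 0.964 with an estimated correlation. Adjusted over the list alone, 5 cell cycle genes and 1 plasma cell gene were lower, against 1 and 1 over all genes, and 0 neutrophil, erythroid, B cell, cytokine and osteoblast genes; over all genes 1 cytokine gene, Cxcl1, passed. Without the infected C3H array the median of inflammatory cytokines and chemokines under Bbaa2Bbaa3 allele was 0.028 (adjusted p = 0.541).

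The called genes of both intervals were spread over the genome. On chromosome 11, 8.46% of tested genes were called for Bbaa4, against 8.71% elsewhere; on chromosome 5, 11.1% were called for Bbaa2Bbaa3, against 8.87% elsewhere. No chromosome passed Fisher's exact test after adjustment (smallest adjusted p 0.155 and 0.300). The 2 comparisons shared 691 genes, 689 in the same direction. The 2 estimates lean on the same C3H arrays and have a correlation of 0.714 by design, so shared genes arise without any effect. With the array set as a block the allele terms could not be estimated, so the array set and the alleles cannot be told apart. Without the infected C3H array, 99 genes were called for Bbaa4 and 38 for Bbaa2Bbaa3, and without the uninfected C3H array 115 and 49.

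The infection by background comparison asked whether lines labelled as C3H and B6 background responded differently. The epidermis list had a higher infection change on the background labelled C3H (median difference 1.44, 21 of 22 members above 0, camera adjusted p = 1.31e-07), as did neutrophil genes (0.83, 15 of 16, adjusted p = 1.31e-07), cell cycle genes (0.33, adjusted p = 0.000112), erythroid genes (0.33, adjusted p = 0.0139), plasma cell genes (0.32, adjusted p = 0.0148) and B cell genes (0.53, adjusted p = 0.0208). The change was lower for pattern recognition genes (-0.36, adjusted p = 0.00878) and cytokine genes (-0.39, adjusted p = 0.0208). With an estimated correlation the adjusted p of these 8 lists ran from 0.474 to 0.842, and adjusted over the list alone 0 of their members passed. The epidermis difference came from B6.C3H-Bbaa2Bbaa3, and without that line the median of epidermis and cornified envelope under infection by background was 0.0074 (adjusted p = 0.687). Of the 8 lists, the neutrophil list alone kept its call whichever line was left out. The interferon-gamma list differed by 0.02 and the type I interferon list by -0.40 (adjusted p = 0.979 and 0.124). No gene passed in limma (smallest adjusted p 1.00; 179 higher and 167 lower at an unadjusted p under 0.05). The higher genes with the smallest p were the chromosomal passenger gene Cdca8 (0.95 ± 0.13, SE), Niban3 (0.89), Brwd1 (0.73), Dennd6b (0.66) and Zfp280d (0.65), and the lower ones the Wnt receptor gene Fzd6 (-0.66 ± 0.11), the fatty acid oxidation gene Ehhadh (-1.09), Coa6 (-0.91), Jpx (-0.58) and the endotoxin coreceptor gene Ly96 (-1.10). The interferon-gamma difference depended on which lines were included, at 2.39 without the line labelled B6.C3H-Bbaa4 and -1.80 without B6.C3H-Bbaa2Bbaa3. With the labels of the 2 Bbaa4 lines exchanged the median of interferon-gamma GTPases and chemokines under infection by background was 3.11. Without the line labelled B6.C3H-Bbaa4, 6 genes passed (Calm4, Dsc1, Gm94, Hrnr, Mt4 and Pof1b).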

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

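The tests of the 3 patterns weighed here and the splits of whole lines were chosen after the results were seen, and the other splits of the samples were planned before they were computed.

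Some genes with strong differences between lines, picked after their values were seen, set the arrays labelled C3H.B6-Bbaa4 beside B6.C3H-Bbaa2Bbaa3, and those labelled B6.C3H-Bbaa4 beside C3H and C3H.B6-Bbaa2Bbaa3. Columns still displaced after reordering are argued against by the lowest Spearman correlation across genes of the 6 arrays with the uninfected C3H array, 0.941. A candidate explanation is that the labels of the 2 Bbaa4 lines were exchanged: 77.8% of the genes that differed by at least 1.5 log2 between the arrays labelled B6.C3H-Bbaa4 and those of C3H.B6-Bbaa2Bbaa3 were on chromosome 5 or 11, against 14.4% of tested genes, as for 2 lines of the same background with different intervals. Between the arrays labelled C3H.B6-Bbaa4 and C3H.B6-Bbaa2Bbaa3 the share was 13%. Lsm12 and Pttg1 on chromosome 11 parted the lines by the Bbaa4 allele only with the labels exchanged, as did Uba6 on chromosome 5 by the Bbaa2Bbaa3 allele. Off chromosomes 5 and 11, 57 genes parted the 2 Bbaa4 lines in the labelled direction and 23 in the opposite one. This direction mixes array set with background. The line labelled C3H.B6-Bbaa4 departed from C3H.B6-Bbaa2Bbaa3, of the same labelled background, in 39 and 23 genes in these directions. The counts therefore do not bear on the labels. Gusb was higher in lines labelled as C3H background. It lies on chromosome 5 and was fixed beforehand for a hypomorphic allele in C3H, so it does not speak for the labels. At 2 log2 or more, 8 of 8 genes that differed between the lines labelled B6.C3H-Bbaa4 and C3H.B6-Bbaa2Bbaa3 were on chromosome 5 or 11. Both lines belong to the same array set. The shares of 77.8% and 8 of 8 cover all tested genes and argue against the different backgrounds that these labels give. An exchange of the 2 Bbaa4 labels as the reason stays open, since it was proposed and tested on the same values.

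The interferon-gamma list had a median infection change of 3.24 to 4.44 in 3 lines and of 0.88 and 0.48 in the lines labelled C3H.B6-Bbaa4 and B6.C3H-Bbaa2Bbaa3. No response in those 2 pools is argued against by the cytokine and chemokine genes at least 2-fold higher, 55% and 40% of the list against 1.25% and 0.704% of all genes. For the line labelled C3H.B6-Bbaa4, array sets processed apart are argued against by a gap of 2.36 between medians within the set of 6 arrays. B6.C3H-Bbaa2Bbaa3 is alone in its set, so this gap does not bear on it. Genetic background with the 2 Bbaa4 labels exchanged may account for it and was not decided, because the 10 ways to part 5 lines are too few for a share under 0.05 (exact permutation p = 0.1, one-sided, the smallest they can give). H2-D1, Pla2g2a and Trim34a part the lines in the same way.

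The allele comparisons called 1172 and 1214 genes over single arrays. With 1 mean per line and 1 residual degree of freedom limma called 0 in each, with 455 and 388 genes at an unadjusted p under 0.05. Differences in genes of the interval's own chromosome as the whole cause are argued against, since 92.1% of Bbaa4 genes were off chromosome 11 and 92.3% of Bbaa2Bbaa3 genes off chromosome 5. Array sets processed apart may account for some of the rest. They cannot be told apart from effects of the alleles on other chromosomes, as 0 of the 2 allele terms can be estimated with the array set in the model. The arrays outside the set of 6 lay all above or all below those 6 in 44.9% of Bbaa2Bbaa3 genes (12.4% of genes not called). For Bbaa4 the shares were 18.1% and 15.1%. With the 2 Bbaa4 labels exchanged, the lines grouped by the Bbaa4 allele are those of C3H and of B6 background. Background is then a further reading of the Bbaa4 genes, which was not decided.

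Other splits of the samples were counted for each comparison, with the real split included. For infection, 16 of 16 splits gave as many genes (real 0, highest other 0) and 5 of 16 as many lists (real 14, highest other 17), and these splits are too few for a share under 0.05. For infection by background the counts were 10 of 10 for genes (real 0, highest other 0) and 8 of 10 for lists (real 8, highest other 11), again too few. Of 100 drawn splits of single arrays, 3 gave as many background genes (real 9, highest other 20), 3 as many Bbaa4 genes (real 1172, highest other 3624) and 3 as many Bbaa2Bbaa3 genes (real 1214, highest other 1622). These shares decide nothing, because such splits part the 2 arrays of a line, which are not independent. Chance is not excluded for lists, where 34 splits gave as many background lists (real 15, highest other 20), 98 as many Bbaa4 lists (real 4, highest other 20) and 88 as many Bbaa2Bbaa3 lists (real 7, highest other 19). With lines kept whole there were 8 splits, too few for a share under 0.05: 4 gave as many background genes (real 9, highest other 8973) and 4 as many lists (real 15, highest other 16), 8 as many Bbaa4 genes (real 1172, highest other 3624) and 8 as many lists (real 4, highest other 15), and 6 as many Bbaa2Bbaa3 genes (real 1214, highest other 3996) and 6 as many lists (real 7, highest other 16). The split of C3H, the line labelled B6.C3H-Bbaa4 and B6.C3H-Bbaa2Bbaa3 against the rest combines the model's own terms, so it repeats the real fit. It was counted above as another split in each background and allele comparison, for single arrays and for whole lines. A split of the 6 reordered arrays against the other 4 gave the 8973 genes, which points to a structure of the samples by array set. With the array set as a block the count of background genes was 0.

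Of 27 groups tested for a sample far from the others, 2 had one, where chance gives about 1 in 20 groups (1.35 here). The epidermis list had a median infection change of -2.69 in B6.C3H-Bbaa2Bbaa3 (gap over range 0.976), and the nerve and Schwann cell list -0.29 in the line labelled C3H.B6-Bbaa4 (0.783). By the interaction test, the infection change differed between labelled C3H and B6 background for the epidermis list by 1.44 (0.0074 without B6.C3H-Bbaa2Bbaa3, for epidermis and cornified envelope under infection by background), neutrophil 0.83, B cell 0.53, cell cycle 0.33, erythroid 0.33, plasma cell 0.32, pattern recognition -0.36, and cytokine and chemokine genes -0.39; with an estimated correlation the adjusted p ran from 0.474 to 0.842.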

How the results depend on the processing

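The alternatives with rows left as deposited, the 4 or 6 arrays alone, unsettled probe sets kept, the array set block, line means with allele terms and exchanged labels were chosen after seeing the data; the others were planned. Signal over background was not measured apart from the values themselves. Over all alternatives, 1507 list tests kept their direction and side of the threshold, 172 became weaker, 94 stronger and 27 reversed, and of the named gene values 7850 kept them, 524 became weaker, 161 stronger and 4 reversed; 171 counts stayed within 1.5 times and 72 moved, and 332 list changes by line stayed and 43 moved. Unless a setting uses fewer genes or arrays, the cause was not tested.

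With an estimated correlation and with fry, 0 lists were called in each of the 5 comparisons (14 under infection, 15 background, 4 Bbaa4, 7 Bbaa2Bbaa3 and 8 infection by background with the preset correlation). Without a filter, infection genes higher were 1, background genes 36, Bbaa4 allele genes 2144, Bbaa2Bbaa3 allele genes 2371, and 1 chromosome passed for Bbaa4. With the upper 40% these were 1 for infection, 645 for Bbaa4 and 646 for Bbaa2Bbaa3, with 65 2-fold falls in B6.C3H-Bbaa2Bbaa3 (115 before). Values as deposited gave 3 background genes, 2115 Bbaa2Bbaa3 genes, 1 list each for Bbaa4 and Bbaa2Bbaa3, 110 2-fold falls in B6.C3H-Bbaa4, as labelled (173 before), and differences of -0.065 (Csf1r Bbaa2Bbaa3 allele) and -0.13 (Hexa Bbaa2Bbaa3 allele). The mean of a gene's probe sets gave 4 background genes, 2 Bbaa4 lists, and Bbaa4 differences of -0.24 for H2-D1 and 0.087 for Nfkb2. Rows left as deposited gave 0 background genes, 18 Bbaa4 genes and 11546 Bbaa2Bbaa3 genes. Background genes were 3 without allele terms and 0 with line means, and line means with allele terms gave 0 background, 0 Bbaa4 and 0 Bbaa2Bbaa3 genes in limma (231, 455 and 388 at an unadjusted p under 0.05; 1 residual degree of freedom). The 6 reordered arrays alone gave 1 infection gene (Saa1). C3H against C3H.B6-Bbaa4 alone gave 4893 genes and against C3H.B6-Bbaa2Bbaa3 alone 4655.

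With the array set as a block, a comparison of C3H.B6-Bbaa2Bbaa3 with the line labelled B6.C3H-Bbaa4 alone, 0 background genes and 9 lists were called, and the medians were -1.04 for type I interferon, -0.74 antigen presentation, -0.38 pattern recognition, -0.18 B cell, 0.10 skeletal muscle, 0.015 epidermis and -0.091 cell cycle genes. With exchanged labels, background genes were 101, and the background medians were 1.17 for interferon-gamma, -0.067 monocyte, 0.057 erythroid, 0.55 skeletal muscle and 0.069 fibroblast genes; the Bbaa4 median of skeletal muscle genes was -0.60; the infection by background medians were 3.11 for interferon-gamma GTPases and chemokines under infection by background, 1.58 type I interferon, 1.07 antigen presentation, 0.0037 cytokine, 0.32 pattern recognition, 0.18 monocyte, -0.12 plasma cell, -0.059 erythroid, 0.18 matrix remodelling and 0.18 endothelial genes.

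Leaving out each line or array gave 0 to 1 infection genes higher (1 without C3H), 0 to 9 background genes, 99 to 948 Bbaa4 allele genes (99 and 115 without the infected and uninfected C3H array), 3 to 9 Bbaa4 lists, 38 to 1096 Bbaa2Bbaa3 allele genes (38 and 49 without those arrays) and 0 to 6 infection by background genes (6 without the line labelled B6.C3H-Bbaa4). For infection by background the medians ran from -1.62 to 0.90 for type I interferon, -1.80 to 2.39 interferon-gamma, -1.01 to 0.48 antigen presentation, -0.52 to 0.11 pattern recognition and -1.02 to 0.14 cytokine genes, lowest without B6.C3H-Bbaa2Bbaa3 and highest without the line labelled B6.C3H-Bbaa4.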

Other observations

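The values in this part were chosen after the data were seen, and no test was added for them. The labels say that skin was removed, and 18 of 22 epidermis genes were at least 2-fold lower after infection in B6.C3H-Bbaa2Bbaa3. The keratin gene Krt25 changed by 6.03 in C3H and by -5.66 in the line labelled C3H.B6-Bbaa4, with lower values of 3.24 and 3.02, near the median of all probe set values (3.22).

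Several genes on chromosomes 5 and 11 had levels that parted the lines. With groups as labelled, Lsm12 and Pttg1 followed the background and Uba6 neither the background nor an interval. With the labels of the 2 Bbaa4 lines exchanged, Lsm12 and Pttg1 part the lines by the Bbaa4 allele, on chromosome 11, and Uba6 by the Bbaa2Bbaa3 allele, on chromosome 5. Lsm12 averaged 7.99 in C3H, 8.04 in the line labelled C3H.B6-Bbaa4 and 8.03 in C3H.B6-Bbaa2Bbaa3, against 4.59 in the line labelled B6.C3H-Bbaa4 and 5.87 in B6.C3H-Bbaa2Bbaa3. Pttg1 averaged 11.97 and 12.38 in the last 2 lines and 9.23 to 10.36 in the first 3. Uba6 averaged 6.88 in the line labelled C3H.B6-Bbaa4 and 6.58 in C3H.B6-Bbaa2Bbaa3, and 8.07 to 8.11 in the other 3.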
